A study of Drosophila melanogaster with 36 samples.

How the data were processed

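Total RNA was taken from abdominal fat body of adult male Drosophila melanogaster, 10 fat bodies pooled for each array, and hybridised to Affymetrix expression arrays after biotin labelling by in vitro transcription, per the labels' protocols. The 36 arrays fall into a WT course of 24 arrays, 1 every 2 h over 2 days, and a dnClk course of 12 arrays, 1 every 4 h over the same span. Time points were not replicated, so the time points of a course serve as the replicates of a fitted 24 h curve. The p-values measure the spread of the arrays around that curve, part of which may be technical.

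The deposited values are probe set intensities on a linear scale, summarised with MAS5 per the submitters' processing notes, which state no version. The authors' scaling left every array with a trimmed mean of 150.0 over all probe sets (2% off each end), so the deposited scaling was kept. No scanner files were used here. All 36 columns of the deposited table matched a sample by name, and no pair of arrays held identical values.

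Control probe sets (183) were set aside and 18769 probe sets remained. Values were analysed as log2(intensity + 16), so a fold change is on that scale and understates the change of dim probe sets. The 60% of probe sets with the highest mean over all arrays were tested, 11261 in all, and the dimmest of them had a mean of 31.3 intensity units. GEO's platform annotation gave 13647 probe sets 1 gene symbol, 402 several and 4720 none. Symbols were updated by Entrez number through a gene table of Drosophila assembly Release 6, in which 13544 of the single-symbol probe sets were found. Only probe sets with 1 symbol were named, and each gene was represented by its probe set with the highest mean, which left 8472 tested genes. No coordinates are given because the sources used here name no genome build for the array.

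Rhythms were fitted in each genotype with limma 3.58.1 in R 4.3.3 as a cosine and a sine of 24 h period, and tested with the moderated F on 2 degrees of freedom. The amplitude is the distance from the fitted mean to the peak in log2 units, and the peak time is given in hours after lights on (ZT). Amplitude and peak time carry delta-method standard errors. WT was also fitted at the 12 times shared with dnClk. The level difference is limma's genotype term in a joint fit with 24 h terms for each genotype, and the difference in rhythm is the moderated F of the genotype by cosine and genotype by sine terms. A day term was tested in WT. All adjusted p-values are Benjamini-Hochberg adjusted over the tested probe sets, with a threshold of 0.05, unless a sentence says that they are adjusted over a list alone. Camera and Fisher exact p-values are adjusted over the 30 gene lists, and permutation p-values of array measures over 13 measures. The interval of the median amplitude ratio of per, tim and vri comes from 10000 draws, with replacement, of the residuals of whole arrays within each genotype.

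The 30 gene lists, the tests and the rule for named genes were fixed before the data were examined. The lists cover clock genes, fat body metabolism, detoxification, immunity, stress, translation and respiration, and markers of fat body and of other cell types. Lists were tested between genotypes with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and among rhythmic genes with a one-sided Fisher exact test against all tested genes. The rule named all core clock genes, the 15 largest WT amplitudes outside them, the 12 most raised and 12 most lowered genes in dnClk, the 12 smallest p-values for a difference in rhythm, and up to 5 further dnClk rhythms, of which there were none. From each list it took up to 4 members with the smallest adjusted p, or up to 2 with the smallest p where none passed. Genes named outside the rule are marked as chosen after their values were seen.

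Array measures were compared between genotypes with two-sided permutation tests of 100000 draws, the smallest possible p being 1e-05. The 13 measures form 1 family.

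On simulated data with the arrays' own means and residual spread (11261 probe sets), limma recovered 65 of 100 rhythms of amplitude 0.5 in WT, 20 of 100 at the 12 shared times and 19 of 100 in dnClk. At amplitude 1 it recovered 84, 62 and 57 of 100. A rhythm of amplitude 0.5 present in WT and absent in dnClk was called different in 24 of 100 cases, and one of amplitude 1 in 72 of 100. Level differences of 0.5 and 1 were recovered in 65 and 87 of 100 cases. Of 10661 unchanged probe sets 13 were called rhythmic in WT, 8 at the shared times, 1 in dnClk, 3 different in rhythm and 7 different in level. The simulated noise was independent between probe sets, which the arrays' noise is not. It also had 1 spread per probe set, shared by both genotypes. The similar recovery at the shared times and in dnClk follows from that setting and does not reflect each genotype's own spread.

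Alternatives fixed before the data were examined were pseudocounts of 1 and 64, no dimness filter, the top 40% of probe sets, quantile normalization, median-centred arrays, mean log2 of the testis and accessory gland lists as covariates, a linear time term, a rank test against cosine templates (JTK-like), added 12 h terms, a residual spread shared over all arrays, single days, the 12 shared times, the ZT as a block, no time terms, and each array left out in turn. Scaling to the hybridisation controls (counts only), leaving out the 6 WT arrays with the most testis signal, covariates in the list test, and an estimated correlation with quantile normalization or with covariates were added after seeing the data. Figures were drawn with matplotlib 3.10.9.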

Results

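The fat body is the fly's main store of lipid and glycogen, and it carries a circadian clock of its own. The series measured transcript levels in abdominal fat body of adult males through 2 days, in flies labelled WT, which carried the transgene UAS-dnClk without a named driver, and in flies labelled dnClk, whose driver is not given in the sources used here. The name dnClk is used for a dominant-negative form of the transcription factor Clock. Flies had been held for 5 days in 12 h of light and 12 h of darkness at 25 °C. WT has 24 arrays at 2 h intervals and dnClk 12 arrays at 4 h intervals. There were no replicates at any time, and the number of arrays limits the precision. The title of the series sets it in the link between circadian clocks, metabolism and reproductive fitness.

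The arrays of the genotypes differed in their technical controls. The bacterial hybridisation controls, added at known ratios, averaged 12.27 ± 0.30 log2 units in WT (SD, n = 24) and 10.21 ± 0.20 in dnClk (SD, n = 12), 4.17-fold lower in dnClk with no overlap between arrays (permutation p = 1e-05, the smallest 100000 draws can give, adjusted p = 1.9e-05 over 13 measures). The log2 ratio of 3′ to 5′ control signal for Act5C was 3.37 ± 0.44 in WT (SD, n = 24) and 1.36 ± 0.32 in dnClk (SD, n = 12), again without overlap (permutation p = 1e-05). For the Gapdh controls it was 3.68 ± 0.55 in WT (SD, n = 24) and 3.21 ± 0.16 in dnClk (SD, n = 12), with overlap (permutation p = 0.0052, adjusted p = 0.0068 over 13 measures). The 99th percentile of intensity was 3541 ± 566 in WT (SD, n = 24) and 1838 ± 126 in dnClk (SD, n = 12; permutation p = 1e-05). Each genotype's arrays form a block of their own in the hybridisation controls, the Act5C ratio and the 99th percentile, so array processing and genotype cannot be told apart.

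Transcripts of testis varied widely between the dissected samples. The mean of 19 testis genes ran from 4.96 to 10.10 log2 units over the WT arrays and from 6.84 to 9.45 over the dnClk arrays. Group means were 7.76 ± 1.70 (SD, n = 24) and 8.36 ± 0.91 (SD, n = 12), and their difference did not pass the permutation test (p = 0.26, adjusted p = 0.28). Accessory gland and ejaculatory tract transcripts averaged 6.48 ± 0.52 in WT and 7.42 ± 0.49 in dnClk (permutation p = 1e-05).

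**Figure D1:**
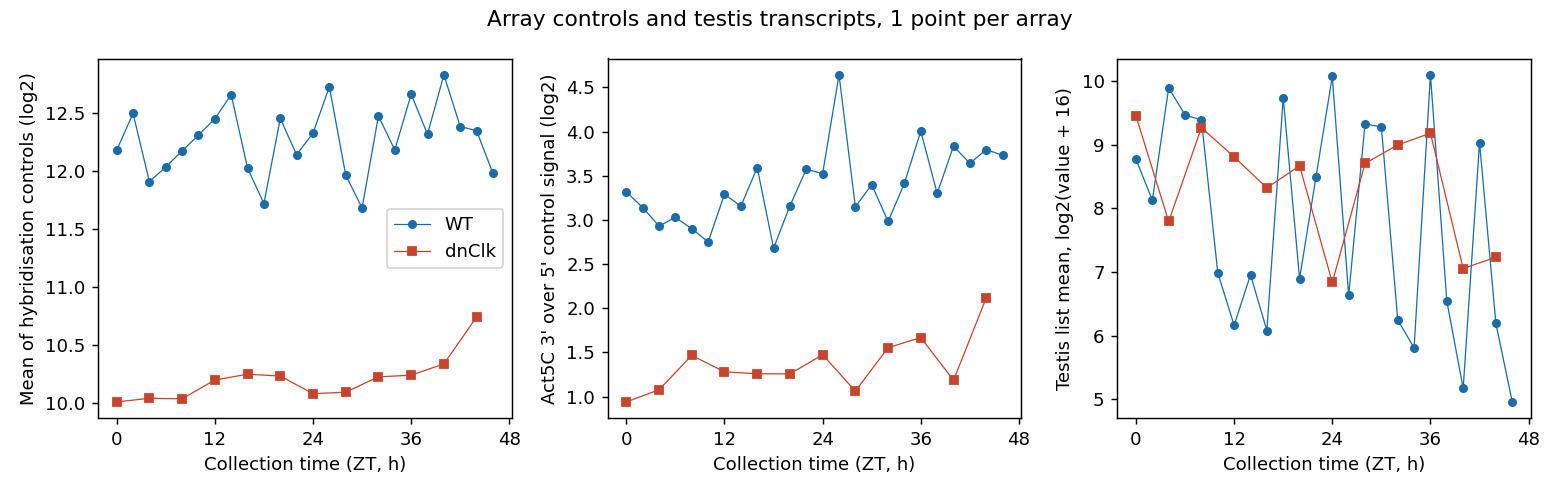
Mean of the bacterial hybridisation controls, ratio of 3′ to 5′ signal of the Act5C controls, and mean of the testis list (all in log2 units) against collection time, 1 point per array, for 24 WT and 12 dnClk arrays. The first 2 measures separate the genotypes without overlap, and the testis mean runs from 4.96 to 10.10 within WT.

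In WT fat body, the clock genes tim, vri and per cycled with peaks in the first part of the night. The transcript of tim (timeless), a repressor within the clock, had an amplitude of 1.60 ± 0.16 log2 units (SE, 24 arrays), a 9.19-fold change from trough to peak, and peaked at ZT 16.4 ± 0.4 h (limma adjusted p = 3.5e-06). For vri, which represses Clk, the amplitude was 1.32 ± 0.11 with a peak at ZT 14.5 (limma adjusted p = 4e-07), and for per (period) it was 1.07 ± 0.10 with a peak at ZT 15.1 (limma adjusted p = 3.3e-06). Clk peaked near dawn, with an amplitude of 0.49 ± 0.09 and a peak at ZT 2.49 (limma adjusted p = 0.023). The remaining core clock genes did not pass the threshold over all probe sets: cry had an amplitude of 0.45 (limma adjusted p = 0.11), cwo 0.43 (0.36), Pdp1 0.30 (0.33) and cyc 0.22 (0.51). Adjusted over the list alone, all 8 core clock genes passed. The second probe set of tim gave an amplitude of 1.01 and a peak at ZT 16.5, and that of cwo 0.40 without passing the threshold (limma adjusted p = 0.39).

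**Figure D2:**
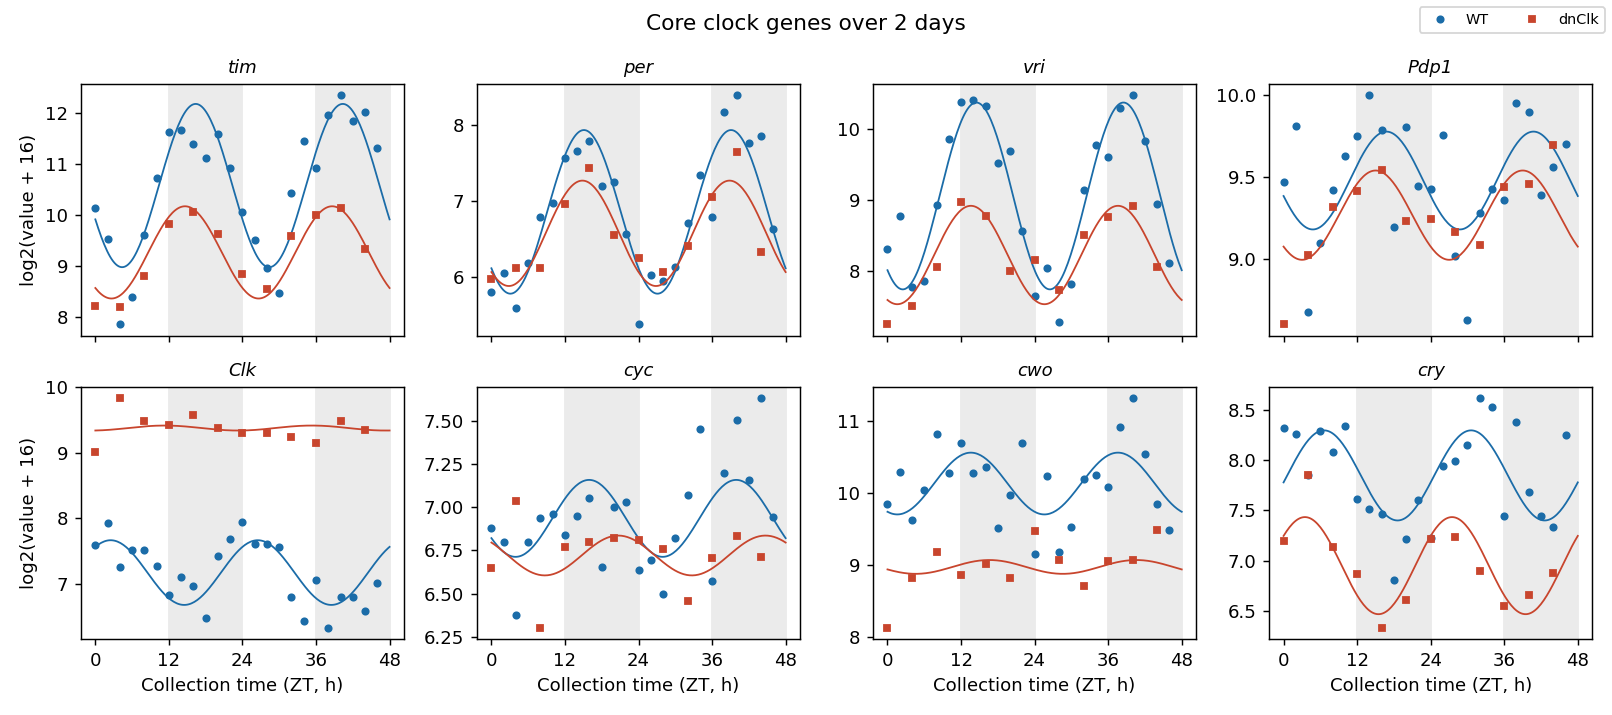
log2(value + 16) of the 8 core clock genes against collection time in WT (circles, 24 arrays) and dnClk (squares, 12 arrays), with the fitted 24 h curves; grey bands mark darkness. In WT tim swings 9.19-fold from trough to peak and in dnClk 3.5-fold, while Clk lies 4.60-fold higher in dnClk, with a fitted amplitude of 0.04.

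Outside the core clock the strongest WT rhythm belonged to Cyp4d21 (sxe1), a cytochrome P450 gene known from screens for sex-biased expression. Its amplitude was 1.62 ± 0.12 with a peak at ZT 16.8 (limma adjusted p = 9.4e-08), a 9.43-fold swing. Several other large rhythms were those of enzymes. CG17562 and CG17560, predicted fatty acyl-CoA reductases, had amplitudes of 1.40 ± 0.11 and 1.17 ± 0.10 and peaked at ZT 3.68 and 3.43. The glycosyltransferase gene Ugt36D1 peaked at ZT 2.94 with an amplitude of 1.1 ± 0.11, and the predicted fatty acid elongase CG18609 at ZT 19.9 with 1.01 ± 0.12. sxe2, a predicted lipase gene also known for sex-biased expression, peaked at ZT 1.84 with an amplitude of 1.18 ± 0.13. Jhe, which encodes juvenile hormone esterase, peaked at ZT 1.60 with an amplitude of 1.06 ± 0.12, and Jhbp1 at ZT 4.76 with 0.89 ± 0.13. The amplitudes of Acsx3, CG10560, e (ebony), geko, Sirup, pippin and CG31205 lay between 0.82 and 1.24, with limma adjusted p from 0.00026 to 0.029.

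In all, 73 of 11261 probe sets were rhythmic in WT, standing for 67 genes, with a median trough to peak change of 2.28-fold. At an unadjusted p under 0.05 there were 968 probe sets, against the 563 that evenly spread p-values would give. The 563 is not a reliable measure of chance for these arrays. Of 100 orders of the WT time points, 3, the real one among them, gave at least 73 probe sets past the adjusted threshold. The highest shuffled order gave 1462. Of the 67 genes, 50 peaked in the dark and 17 in the light. The count depended on the array at ZT 36, WT replicate 19, which had the highest testis signal: without it 196 probe sets were rhythmic, all 73 among them. It rose to 167 with the residual spread shared between genotypes, and fell to 29 with arrays centred on their medians and to 9 on either day alone.

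**Figure D3:**
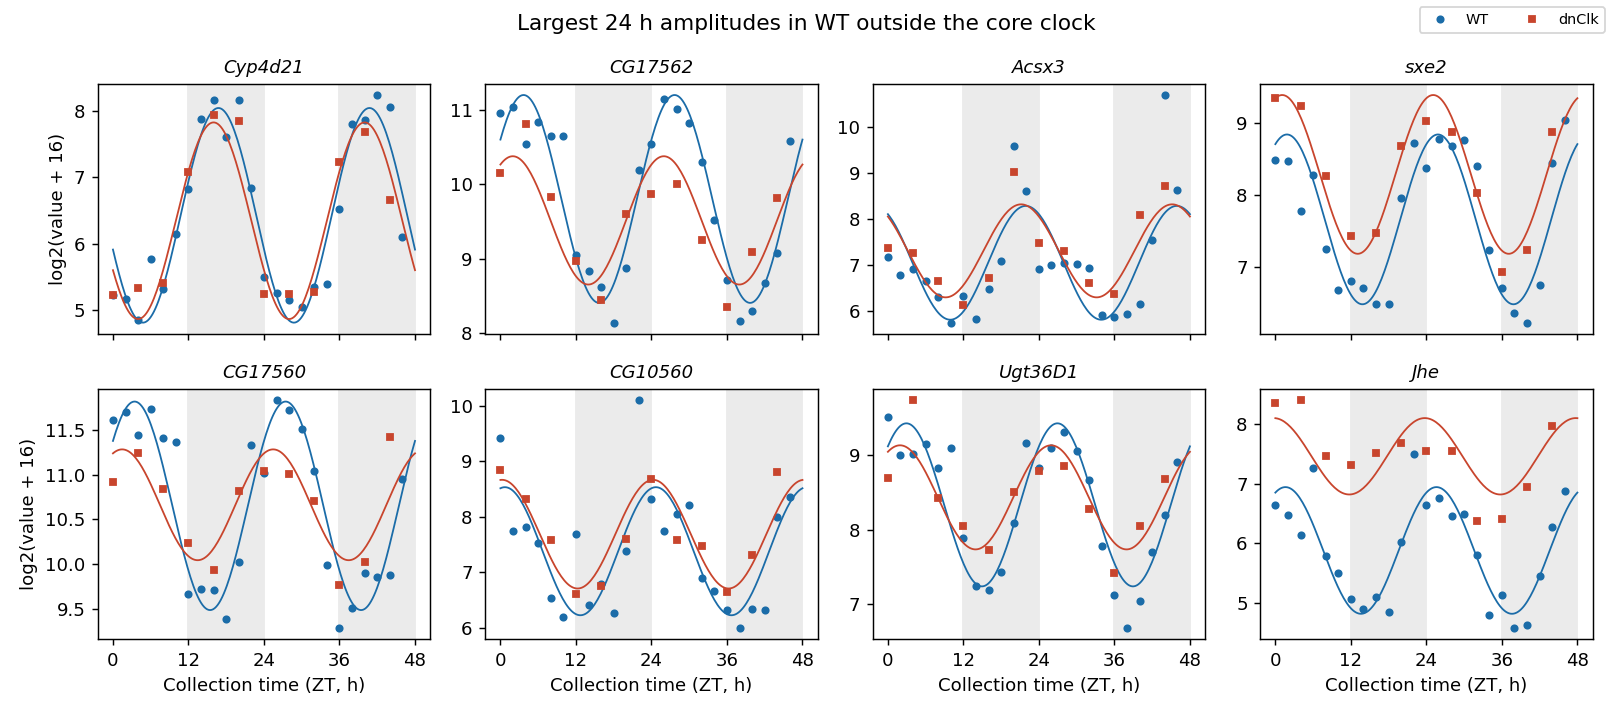
log2(value + 16) against collection time for the 8 genes outside the core clock with the largest WT amplitudes, in WT (circles, 24 arrays) and dnClk (squares, 12 arrays), with the fitted 24 h curves; grey bands mark darkness. Cyp4d21 and sxe2 swing by similar amounts in both genotypes (amplitudes 1.62 and 1.48, and 1.18 and 1.1).

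Among the 30 gene lists, the core clock (4 of 8 genes, Fisher exact adjusted p = 7e-06) and the yolk protein and sex-biased fat body genes (2 of 8, Cyp4d21 and sxe2, Fisher exact adjusted p = 0.025) held more WT-rhythmic genes than the background of 67 in 8472. Cytochrome P450 genes contributed Cyp4d21, Cyp6a21 and Cyp6a20, 3 of 65 (Fisher exact adjusted p = 0.15). The UDP-glycosyltransferase, odorant-binding and takeout-like, and oenocyte lists held 1 rhythmic gene each (Ugt36D1, CG7079 and CG18609). Genes are not independent, so these p-values are descriptive. Adjusted over the list alone, 8 core clock, 7 cytochrome P450, 3 oenocyte, 2 UDP-glycosyltransferase, 2 heat shock, 2 yolk and sex-biased, 1 insulin and TOR, 1 antioxidant, and 1 odorant-binding and takeout-like gene passed. Over all probe sets no gene passed in the other 24 lists, which include glycogen and trehalose, glycolysis, fatty acid synthesis and lipolysis. In those metabolic lists the smallest values were for Acsl (amplitude 0.34, limma adjusted p = 0.32) and whd (amplitude 0.38, limma adjusted p = 0.36).

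In dnClk fat body only a few transcripts passed the threshold, led by the sex-biased genes. sxe2 cycled with an amplitude of 1.1 ± 0.10 (SE, 12 arrays) and a peak at ZT 1.09 (limma adjusted p = 0.0076), Cyp4d21 with 1.48 ± 0.16 and a peak at ZT 15.99 (limma adjusted p = 0.024), and tim with 0.90 ± 0.11 and a peak at ZT 14.6 (limma adjusted p = 0.031). The second tim probe set also passed, which makes 4 probe sets, all of them rhythmic in WT too. per and vri kept amplitudes of 0.69 ± 0.10 each with limma adjusted p = 0.23, and 0.00032 for each when adjusted over the list alone. cry, at 0.48 ± 0.09 in dnClk and 0.45 ± 0.11 in WT, also passed over the list alone (limma adjusted p = 0.0012, and 0.48 over all probe sets), while Pdp1, at 0.27 ± 0.09 in dnClk and 0.30 ± 0.09 in WT, did not (0.056). Clk had an amplitude of 0.04 ± 0.09 (limma adjusted p = 0.98). Over all probe sets 194 had an unadjusted p under 0.05, below the 563 that evenly spread p-values would give. The JTK-like test and the fit with 12 h terms called 0 probe sets, and leaving out single dnClk arrays gave between 1 and 5. The count was 1 without the array at ZT 8, 12, 16, 28, 36 or 40, and 2 without that at ZT 0 or 20.

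At the 12 shared times, with as many arrays as dnClk, WT had 10 rhythmic genes: Cyp4d21, CG17562, vri, CG31205, Ugt36D1, Jhe, CG17560, tim, CG13833 and spin. This count was unstable. It was 896 without the WT array at ZT 36, 3 without that at ZT 0 or 28, 5 without that at ZT 8, 12, 20, 24 or 40, and 6 without that at ZT 4, 16 or 44. The JTK-like test called 0, with 905 probe sets at an unadjusted p under 0.05 in limma. Whether rhythms differed between the genotypes was tested directly.

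The clock transcripts tim, vri and per had smaller fitted amplitudes in dnClk than in WT as deposited. The fitted amplitude of tim was lower by 0.70 log2 units (95% interval of dnClk minus WT -1.07 to -0.33), and that of vri by 0.62 (-0.92 to -0.33). Adjusted over the list alone, tim, vri and Clk, 3 of the 8 core clock genes, differed in rhythm (limma adjusted p = 0.014, 0.014 and 0.016). That test takes amplitude and peak time together and is not a test of amplitude alone. Clk had a fitted amplitude of 0.49 in WT and 0.04 in dnClk, but its signal was 4.60-fold higher in dnClk, and a constant signal added to it would lower its amplitude on the log2 scale with the endogenous rhythm unchanged. After quantile normalization the limma adjusted p over the list alone was 0.048 for tim, 0.064 for vri and 0.048 for Clk. The fitted amplitude of tim was then 1.40 ± 0.13 in WT and 1.13 ± 0.13 in dnClk (SE). Its difference of -0.27 is not clearly resolved by those errors, while vri differed by -0.45 and per by -0.47. With median-centred arrays the limma adjusted p over the list alone was 0.062 for tim, 0.019 for vri and 0.18 for Clk. For per the amplitude difference was -0.38 ± 0.14 (SE), with a 95% interval of -0.67 to -0.098. The joint test of its rhythm gave a limma adjusted p of 0.16 over the list alone. cry (0.16), cyc (0.30), cwo (0.30) and Pdp1 (0.66) did not pass either. The peak of tim came 1.74 ± 0.58 h earlier in dnClk by the fitted curves, that of vri 0.89 ± 0.66 h and that of per 0.25 ± 0.67 h. On the first day alone 0 core clock genes passed, and on the second day 1.

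Over all probe sets, limma called 0 differences in rhythm. At an unadjusted p under 0.05 were 179 probe sets, below the 563 that evenly spread p-values would give. The smallest adjusted p was 0.095, for Ag5r, whose amplitude was 0.23 in WT and 0.69 in dnClk. Next came Drsl5 (limma adjusted p = 0.33), a drosomycin-like gene with amplitudes of 0.61 and 0.12, and CG14696 (limma adjusted p = 0.66). Drsl5 signal was 7.72-fold higher in dnClk, so the limit given above for the log2 amplitude of Clk holds for Drsl5 too. Ag5r signal was 23.8-fold higher in WT, so the same limit holds for its WT amplitude. Cont, CG11367, Listericin, CG17560, CG17562, whe, slv, Cyp6a20 and Mal-B1 followed with limma adjusted p = 0.98. The acyl-CoA reductase genes among these, CG17562 and CG17560, had amplitudes of 0.86 and 0.62 in dnClk against 1.40 and 1.17 in WT. With the testis and accessory gland means as covariates, 2 probe sets passed, and 1 passed without the dnClk array at ZT 24 or that at ZT 32.

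More probe sets were called different between the genotypes in mean level than in rhythm, by tests of unlike power. On the simulated data a level difference of 0.5 was recovered in 65 of 100 cases. A rhythm of amplitude 0.5 absent in dnClk was recovered in 24 of 100. The level term is also confounded with array processing. Clk signal was 4.60-fold higher in dnClk (9.37 ± 0.21 against 7.17 ± 0.47 log2 units, SD, n = 12 and 24; limma adjusted p = 1.8e-18), in the genotype named for a Clk transgene. Other clock genes were lower in dnClk: tim 2.48-fold (limma adjusted p = 5.3e-08), cwo 2.23-fold (1.1e-07), cry 1.86-fold (6.1e-08), vri 1.78-fold (7.6e-07), per 1.22-fold (0.039) and cyc 1.16-fold (0.040). Pdp1 had a difference of -0.21 (limma adjusted p = 0.075). The second probe sets of tim and cwo were also lower, by -0.48 and -0.64. As a list, the core clock lay 0.78 below the median of all genes (camera adjusted p = 0.023), which did not hold with an estimated correlation (adjusted p = 0.39), after quantile normalization (adjusted p = 0.15) or with the tissue covariates (adjusted p = 0.064).

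The largest differences exceeded 16-fold on the scale with the pseudocount of 16. Among the genes highest in dnClk was Cyp4p2, a cytochrome P450 gene, at 10.65 ± 0.30 against 5.14 ± 0.32 (SD, n = 12 and 24), 45.6-fold higher (limma adjusted p = 2.1e-28). CG7763 (43.7-fold), CG15865 (43.3-fold), LysX (41.7-fold), CG3513 (37.7-fold), CG9689 (32.7-fold), the glutathione transferase gene GstD2 (31.7-fold) and lectin-24A (28.8-fold) were others, with CG44251, CG3987, CG3604 and CG9686 also among the 12. LysP was 51.0-fold lower, at 5.14 ± 0.93 in dnClk against 10.81 ± 0.45 in WT (limma adjusted p = 1.9e-21). LysP and LysX belong to a family of closely related lysozyme genes. CG16826 was 48-fold lower, Ag5r 23.8-fold, nompA 21-fold, the one-carbon enzyme gene Gnmt 18.9-fold, whe 15.3-fold and Cyt-b5-r 14.4-fold, with CG33109, CG13947, CG14823, Odc1 and Mal-B1 completing the 12. In all, 31 genes differed by over 16-fold. Where a gene's signal in the lower genotype is near background, its fold and its rank depend on the pseudocount: with a pseudocount of 1 and of 64 the log2 difference was 6.34 and 4.31 for Cyp4p2, 6.91 and 3.90 for CG15865, and -7.03 and -4.41 for LysP.

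Over all probe sets, 4428 were higher and 1991 lower in dnClk (limma, 57.0% of those tested). The split between directions rests on the scaling: quantile normalization gave 2278 higher and 2957 lower, and median-centred arrays 1291 and 3822. Scaling to the hybridisation controls, an alternative added after seeing the data, gave 11090 higher and 70 lower, and 53 of the 82 named genes that were lower as deposited became higher. Lower and higher are therefore relative to the total signal of an array. The median log2 difference of all probe sets was 0.25 as deposited, -0.013 after quantile normalization, -0.14 after centring and 2.00 with control scaling. In 5 groups of probe sets by brightness the median difference was 0.31 in the dimmest and -0.20 in the brightest. Such groups are too coarse for the very brightest probe sets: the 99th percentile was 3541 in WT and 1838 in dnClk. Quantile normalization moved the difference of the bright genes apolpp and Cyp4g1 from -1.15 and -1.33 to 0.030 and 0.010. Of 3800 probe sets called in both settings, 1665 were lower in both. List values below are given relative to the median of all genes, which does not remove this trend with brightness, so a list of bright genes can lie lower for that reason alone. The folds of single bright genes carry the same limit. Each list is named with its quantile-normalized test where that ends the call.

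Genes of carbohydrate and fat metabolism, which the fat body expresses strongly, lay lower in dnClk. Of 15 glycolysis and gluconeogenesis genes 11 were lower and 0 higher (11 passed when adjusted over the list alone), among them Hex-C (10.9-fold), Pepck1 (7.06-fold), fbp (5.68-fold) and Gpdh1. The list median lay 0.99 below that of all genes (camera adjusted p = 1.3e-07; adjusted p = 0.14 with an estimated correlation). In the glycogen and trehalose list 7 of 10 genes were lower and 2 higher (9 passed when adjusted over the list alone), with Pgm1 5.18-fold lower, the adipokinetic hormone receptor gene AkhR 4.77-fold and the trehalose synthesis gene Tps1 3.19-fold (camera adjusted p = 0.00051; adjusted p = 0.33 with an estimated correlation). Of 18 fatty acid and triglyceride synthesis genes 14 were lower and 2 higher (16 when adjusted over the list alone), including FASN1, which encodes fatty acid synthase (3.14-fold), Men (3.14-fold) and Desat1 (2.30-fold; camera adjusted p = 7.7e-08; adjusted p = 0.14 with an estimated correlation). Nucleotide and one-carbon metabolism had 10 of 18 genes lower and 1 higher (11 when adjusted over the list alone), led by Gnmt and Paics (5.70-fold; camera adjusted p = 1.2e-05; adjusted p = 0.25 with an estimated correlation). Of 64 respiratory chain genes 49 were lower and 3 higher (52 when adjusted over the list alone), such as ND-MLRQ (2.79-fold) and ATPsynCF6 (3.0-fold; camera adjusted p = 4.6e-16; adjusted p = 0.14 with an estimated correlation). Fat body markers had 9 of 11 genes lower and 0 higher (9 when adjusted over the list alone), with a median 1.75 below that of all genes (camera adjusted p = 2.4e-08; adjusted p = 0.14 with an estimated correlation). This list shares 5 genes with the lipid droplet list, 3 with the storage list, 2 with glycogen and trehalose, 1 with glycolysis and 1 with fatty acid synthesis, so it is not separate evidence.

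**Figure D4:**
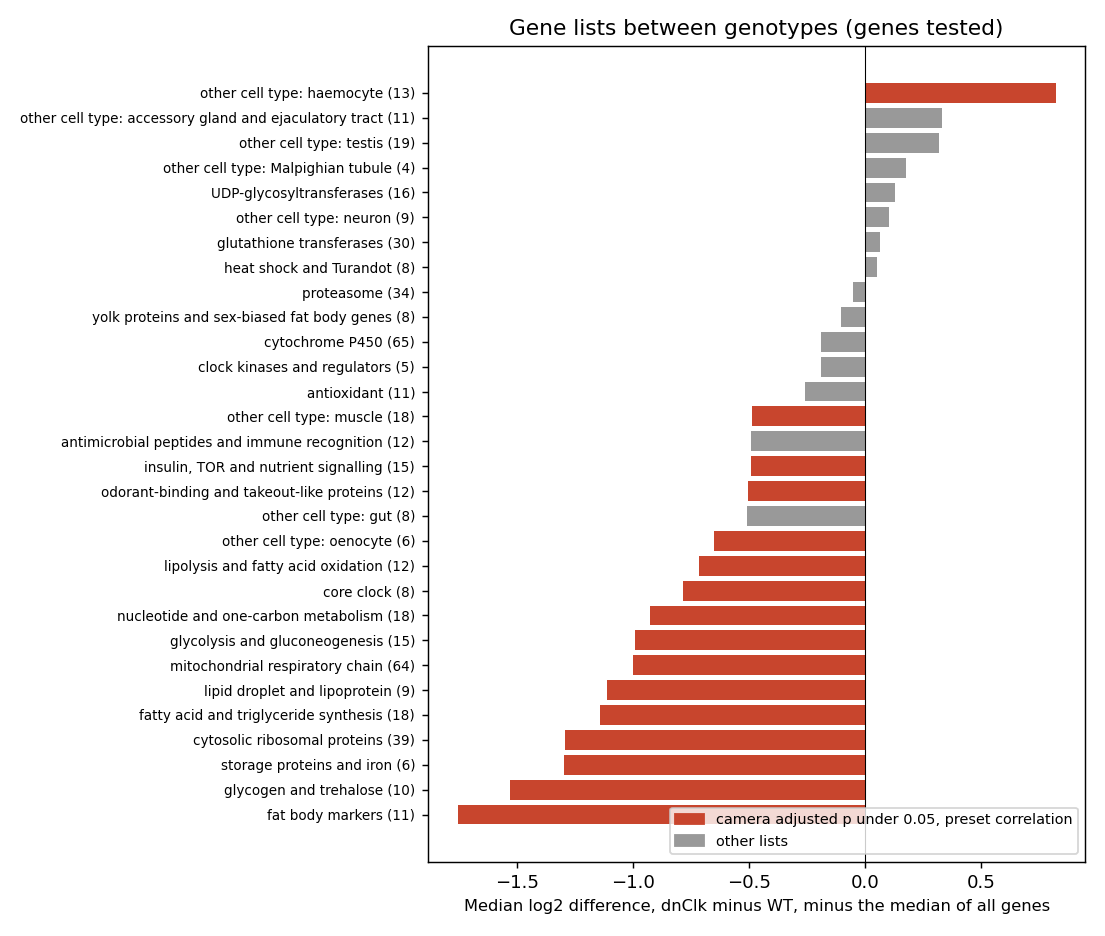
Median log2 level difference (dnClk minus WT) of each gene list relative to the median of all 8472 genes, with the number of genes tested; red bars have a camera adjusted p under 0.05 at the preset correlation. Fat body markers lie lowest at -1.75 and haemocyte markers highest at 0.82; with an estimated correlation 0 lists pass, and after quantile normalization 6 lists turn direction: muscle, which passes as deposited, proteasome, which passes only after it, and cytochrome P450, heat shock and Turandot, antioxidant and Malpighian tubule, which pass in neither.

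Other lists that lay lower as deposited lost their call after quantile normalization. Of 39 cytosolic ribosomal protein genes 30 were lower and 2 higher (32 when adjusted over the list alone), for example RpL41 (2.56-fold lower) and RpS27A (2.34-fold), with a camera adjusted p = 1.1e-18, an adjusted p = 0.14 with an estimated correlation and an adjusted p = 0.77 after quantile normalization. Lipolysis and fatty acid oxidation had 9 of 12 genes lower, including the lipase gene bmm (2.39-fold) and wal (2.34-fold), with a camera adjusted p = 0.00059, an adjusted p = 0.43 with an estimated correlation, 0.082 after quantile normalization and 0.10 with the tissue covariates. In the lipid droplet and lipoprotein list 6 of 9 were lower, with the perilipin genes Lsd-1 (2.88-fold) and Lsd-2 (2.49-fold), and Seipin was 3.65-fold higher (camera adjusted p = 0.0060; adjusted p = 0.40 with an estimated correlation; 0.57 after quantile normalization). Storage and iron proteins had 4 of 6 lower, among them Lsp2 (6.80-fold) and Tsf1 (4.46-fold; camera adjusted p = 0.0011; adjusted p = 0.14 with an estimated correlation; 0.22 after quantile normalization), while Fer1HCH and Fer2LCH turned direction under that scaling. Insulin, TOR and nutrient signalling had 7 of 15 lower and 1 higher, among them tobi (12.0-fold lower), Pdk1 (1.82-fold) and foxo (1.76-fold; camera adjusted p = 0.016; adjusted p = 0.52 with an estimated correlation; 0.10 after quantile normalization). Odorant-binding and takeout-like proteins had 5 of 12 lower, with Obp99c 2.58-fold (camera adjusted p = 0.023; adjusted p = 0.18 with an estimated correlation; 0.60 after quantile normalization; 0.15 with the tissue covariates). Adjusted over the list alone, 9, 7, 5, 9 and 5 genes of these last lists passed.

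Markers of other cell types moved in different directions. Of 13 haemocyte (blood cell) genes 11 were higher in dnClk and 2 lower (13 when adjusted over the list alone), with NimB4 7.5-fold, He 6.05-fold and NimC1 4.93-fold higher and Nplp2 3.25-fold lower (camera adjusted p = 0.0017; adjusted p = 0.26 with an estimated correlation). Muscle genes had 10 of 18 lower and 3 higher (14 when adjusted over the list alone), among them Zasp66 (1.92-fold lower; camera adjusted p = 0.0094; adjusted p = 0.57 with an estimated correlation), and that list's direction turned after quantile normalization (adjusted p = 0.22). Oenocyte genes had 4 of 6 lower, with Cyp4g1 2.52-fold and CG18609 2.30-fold (camera adjusted p = 0.012; adjusted p = 0.18 with an estimated correlation; 0.93 after quantile normalization, where Cyp4g1 turned direction). Accessory gland and ejaculatory tract genes had 9 of 11 higher, including EbpII (5.81-fold) and Dup99B (3.64-fold), without a list call (camera adjusted p = 0.21). Testis (2 of 19 higher, camera adjusted p = 0.86), gut (LysX higher and LysP lower of 8, 0.44), Malpighian tubule (1 of 4 higher, 0.96) and neuron markers (6 of 9 higher and 1 lower, 0.86) gave no list call.

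Detoxification and stress genes changed singly more than as lists. Of 30 glutathione transferase genes 15 were higher and 5 lower (20 when adjusted over the list alone), with GstD9 4.36-fold higher beside GstD2 (camera adjusted p = 0.18 as deposited, 0.00045 after quantile normalization, 0.019 with the tissue covariates; with an estimated correlation, adjusted p = 0.63, 0.53 and 0.37 in turn). Cytochrome P450 genes went both ways, 24 of 65 higher and 25 lower (50 when adjusted over the list alone; camera adjusted p = 0.26), with Cyp6d2 7.77-fold higher and Cyp6g1 8.48-fold lower. UDP-glycosyltransferases had 7 of 16 higher and 3 lower (camera adjusted p = 0.44), with Ugt317A1 2.77-fold higher. The antimicrobial list had 2 of 12 higher and 4 lower (0.053), with BomS2 2.98-fold lower. Heat shock and Turandot genes had 5 of 8 higher and 3 lower (0.88), with Hsp26 3.66-fold higher and TotC 6.63-fold lower. Antioxidant genes had 2 of 11 higher and 4 lower (0.44), with Trxr1 2.28-fold higher. The yolk protein and sex-biased list had 4 of 8 higher and 2 lower (0.86), with fit 7.68-fold lower. Proteasome genes had 8 of 34 higher and 7 lower (0.44 as deposited, and higher as a list at 0.00039 after quantile normalization; with an estimated correlation, adjusted p = 0.93 and 0.69 in turn). Clock kinases and regulators had 2 of 5 higher and 1 lower (0.75), with slmb 1.35-fold higher and wdb 1.26-fold lower. Adjusted over the list alone, 11 UDP-glycosyltransferase, 6 antimicrobial, 8 heat shock, 6 antioxidant, 6 yolk and sex-biased, 15 proteasome and 3 clock kinase genes passed.

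Between the 2 days of the WT course, 44 probe sets were higher and 221 lower on day 2 (limma). Among genes chosen after their values were seen, the one-carbon enzyme genes Nmdmc and Shmt were higher on day 2 by 1.45 ± 0.33 and 1.24 ± 0.28 log2 units (SE, 24 arrays; limma adjusted p = 0.030 and 0.029), and the peptidoglycan recognition gene PGRP-SB1 by 1.36 ± 0.35 (0.045). The transporter gene Gat fell by 1.04 ± 0.17 (limma adjusted p = 0.0067). The count was not stable: leaving out 1 array moved it by over 1.5 times for 17 of the 24 arrays, to 29 without that at ZT 14, 20 or 44, 1028 without that at ZT 36 and 1181 without that at ZT 26. It was 6 with median-centred arrays and 2457 with the testis and accessory gland means as covariates.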

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

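Except for the probe-pair test, the comparison of 3′ to 5′ ratios with the first component, and the splits and shuffled orders, the tests in this part were chosen after the results they bear on had been seen.

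The rhythm of 3 core clock genes differed between the genotypes, adjusted over the core clock list alone: Clk (limma adjusted p = 0.016), tim (limma adjusted p = 0.014) and vri (limma adjusted p = 0.014). Over all probe sets the same test passed for none of these (adjusted p = 0.98). Among rhythmic core clock genes other than Clk, whose signal the transgene may add to, the dnClk to WT amplitude ratios were 0.64 for per, 0.56 for tim and 0.53 for vri, and their median was 0.56 as deposited (95% interval 0.42 to 0.75, from resampled residuals of whole arrays) and 0.63 with tissue covariates. The fitted amplitude of cry was 0.45 in WT and 0.48 in dnClk, and that of Pdp1 0.30 and 0.27.

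The smaller fitted amplitude of tim, vri and per was weighed against losses of signal range, tissue RNA and a general damping, by their amplitude ratios. The difference in rhythm of per did not pass (limma adjusted p = 0.16 over the list alone). The step between the lowest and the highest hybridisation control was 0.13 log2 units longer in dnClk, which argues against loss of range at the scanner over the span of those controls, but the signal of the dnClk arrays was narrower (99th percentile 1838 against 3541, median 58.2 against 41.7), and after quantile normalization the ratios were 0.81 ± 0.12 for tim, 0.63 ± 0.11 for vri and 0.59 ± 0.13 for per (SE). Their median of 0.63 had a 95% interval of 0.48 to 0.89, and with the testis and accessory gland means as covariates the median of 0.63 had one of 0.49 to 0.81 (where tim and vri still differed in rhythm, limma adjusted p = 0.0033 and 0.013 over the list alone), so both, unlike the interval as deposited, reach the bound of 0.8, the covariate one only just, and the parts of a narrower signal and of tissue RNA cannot be told apart from a smaller rhythm by these ratios. Among 46 genes outside the core clock, taken from the 50 smallest p-values on the WT arrays at unshared times and projected onto the phase fitted there, the median ratio on the other arrays was 0.50 (95% bootstrap interval 0.29 to 0.61), which includes the clock genes' 0.49, although 11 of the 46 had a ratio over 0.8 (the ratio of median amplitudes, computed first, was 0.45 against 0.48). A damping of rhythmic transcripts in general, whether by the transgene or by array processing, therefore may account for it and stays open. The 46 genes were taken by rank of p, and some kept no WT rhythm on the other arrays. Projected WT amplitudes there were -0.15 for Gdap1 and -0.033 for Rubicon, so the ratios of such genes do not measure damping.

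In level 6419 probe sets differed. Of 100 splits of the 36 arrays 1 gave as many, the real one, and the highest other gave 1. Random splits of the arrays thus rarely give such a count, as far as 100 splits can show. Array processing remains possible: the hybridisation controls differed by -2.06 log2 units without overlap. That fits labelling or hybridisation that differed between the genotypes' arrays and is confounded with genotype. Of 237 genes with 2 or more called probe sets, 19.4% had probe sets called in opposite directions, between the bounds of 5 and 20% set for a 3′ bias, so its part cannot be told apart from that of the genotype. The share of testis and accessory gland RNA as the whole cause is argued against by the 4922 probe sets that passed with both lists as covariates. No other tissue list was used as a covariate. The haemocyte list mean was 7.26 ± 0.17 in WT (SD, n = 24) and 8.26 ± 0.15 in dnClk (SD, n = 12). It separated the genotypes without overlap (permutation p = 1e-05). The shares of RNA from other tissues and from fat body itself, genotype and fly background stay open, untested.

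The WT arrays differed from each other more than the dnClk arrays did, with a first component that held 67.0% of the variance. The testis list mean correlated with that component, computed without the list, at r = 0.98 (rho = 0.98, permutation p = 1e-05 for each, the smallest possible, adjusted 2e-05 over 2 relations; r = 0.98 without the 2 arrays farthest from the median), which fits testis tissue in some dissected samples. The 3′ to 5′ ratio of Act5C gave r = -0.23 (rho = -0.27, permutation p = 0.30 and 0.21, adjusted 0.30 and 0.21; r = -0.43 without 2 arrays). With all arrays this lay within the bound set against RNA degradation or incomplete labelling as the main source. Without the 2 arrays it did not, so that explanation is not settled. The Gapdh ratio was not compared with the component. A 24 h curve explained 17.2% of the variance of the testis mean in WT (permutation p = 0.14), which argues against time of day. No other biological explanation of this spread was tested.

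The counts of splits and orders here include the real one. For a difference in rhythm, 1 of 100 splits, the real one, had a lowest adjusted p of 0.095, and the smallest of the others was 0.12. A split that mixes the genotypes leaves their level differences in the residual spread. The real split is thereby favoured, so this comparison cannot show whether the rhythms differ. For the day difference in WT, 1 of 100 splits, the real one, gave 265, and the highest other gave 0. With time points shuffled, 3 of 100 orders, the real one among them, gave at least the 73 rhythmic probe sets of WT, and 3 of 100, the real one among them, at least the 10 at the shared times. The highest shuffled counts were 1462 and 1510, many times the real ones, and why some orders gave so many was not tested. In dnClk 1 of 100 orders reached 4, the real one, and the highest other count was 1.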

How the results depend on the processing

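The scaling to hybridisation controls and the omission of 6 WT arrays were chosen after seeing the data. Where no cause is named, the cause was not tested. Signal over background limits dim probe sets, which the pseudocount compresses.

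Rhythmic probe sets in WT (73) numbered 29 with median-centred arrays, 167 with a shared residual spread, 9 on the first day and 9 on the second (fewer arrays), and 53 to 196 with single arrays left out. At the shared times (10) they numbered 5 with pseudocount 1, 0 median-centred, 4 with a linear time term, 0 by the JTK-like test, 1 with 12 h terms, 55 with a shared spread, and 3 to 896 with single arrays left out. In dnClk (4) they numbered 2 with the top 40% of probe sets, 2 median-centred, 1 with linear time, 0 by the JTK-like test, 0 with 12 h terms, and 1 to 5 with single arrays left out. Differences in rhythm (0) numbered 2 with tissue covariates and 0 to 1 with single arrays left out. Core clock genes differing in rhythm (3) numbered 1 median-centred, 0 on the first day and 1 on the second.

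Probe sets higher in dnClk (4428) numbered 7227 without the dimness filter and 2778 in the top 40% (different numbers tested), 2278 after quantile normalization and 1291 median-centred; those lower (1991) numbered 3822 median-centred. Scaling to the controls gave 11160 in all, 11090 higher and 70 lower, and 53 of 82 named genes that were lower became higher. Between the main setting and quantile normalization, 3800 probe sets passed in both, 108 of them in opposite directions. Day differences (265) numbered 59 after quantile normalization, 6 median-centred, 2457 with tissue covariates, and 29 to 1181 with single arrays left out. Lists between genotypes (16) numbered 0 with estimated correlation, 9 after quantile normalization, and 0 with estimated correlation after quantile normalization or with tissue covariates, both added after seeing the data. The other counts stayed within 1.5 times, including those without the 6 WT arrays.

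After quantile normalization the level difference turned to -0.11 for Fbxl4, 0.030 for apolpp, 0.068 for Hsc70-3, 0.13 for Cat, 0.14 for Fer2LCH, 0.068 for Fer1HCH, 0.34 for Prosbeta7, -0.015 for mia, 0.17 for Mf, 0.010 for Cyp4g1, 0.30 for spidey and -0.048 for brp, and of the lists past the threshold in either setting the direction of the proteasome (adjusted p = 0.00039) and muscle lists (0.22; 0.93 with estimated correlation) turned. Median-centred it turned to -0.13 for Cont, -0.38 for CG17560, -0.20 for Fbxl4, -0.041 for mia, -0.062 for brp and -0.057 for futsch, and with tissue covariates to -0.15 for Mst57Da and -0.17 for Appl.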

Other observations

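The genes named here were chosen after their values were seen, and no test of a group or of a difference between peak times was made on them. The elongase-like gene CG9459 had an amplitude of 0.53 ± 0.08 in WT (SE, 24 arrays; limma adjusted p = 0.0034) with a peak at ZT 19.3, and the predicted acyl-CoA reductase gene CG1441 of 0.54 ± 0.10 (limma adjusted p = 0.017) with a peak at ZT 22.3. CG13833, CG42329 and CG31189 had dnClk amplitudes of 0.82, 1.1 and 0.50 against WT amplitudes of 0.80, 0.62 and 0.51. None of them passed the threshold in dnClk (limma adjusted p = 0.25, 0.25 and 0.27). Of the 67 WT-rhythmic genes 33 had an unadjusted p under 0.05 in dnClk, and 32 of these peaked within 4 h of their WT time, with a median shift of -0.74 h and 25 earlier in dnClk. These genes passed a separate fit in each genotype, and neither fit prefers a peak time. How often unrelated rhythms would peak within 4 h was not tested, and the other WT-rhythmic genes are not counted here.

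Tsp2A was higher by 4.29 ± 0.13 log2 units (SE, 36 arrays; limma adjusted p = 8e-24), mesh by 4.01 ± 0.17 (limma adjusted p = 7.8e-20) and Ssk by 2.51 ± 0.18 (limma adjusted p = 3.7e-14) in dnClk, 3 genes known from the smooth septate junction, and the chitin synthase gene Chs2 by 3.77 ± 0.17 (limma adjusted p = 1.9e-19). hoka, another junction gene, differed by 0.04 ± 0.16 (limma adjusted p = 0.82). The mean of the gut list fixed beforehand, mostly digestive enzymes, was 7.82 ± 1.0 in WT (SD, n = 24) and 7.55 ± 0.91 in dnClk (SD, n = 12; permutation p = 0.43), and neither that list nor the Malpighian tubule list gave a call between genotypes. Only 8 gut genes and 4 tubule genes were tested, and the gut mean varied widely. These lists could have missed a difference and leave the shares of gut and tubule RNA open.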
